A study of Homo sapiens with 25 samples.

How the data were processed

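The authors processed the reads with kallisto against GRCh38, according to the processing notes of the submitters, and neither a version nor an annotation is given in the sources used here. The deposited tables hold, per gene and library, the authors' TPM values from kallisto, summarised from transcripts to genes in the form tximport writes. The same deposited tables hold the authors' estimated counts, which were not scaled between samples, and the average effective transcript length in bases that the authors' summary step gave. The TPM columns sum to 793579 to 973631, less than a complete table would, for a reason that was not tested, and TPM is used for levels and the estimated counts for tests. Cord blood-derived and tissue tables list 34887 genes each, the peripheral blood-derived table lists 39749, and 28404 symbols are in both kinds of table. Every value column was matched to a sample by its title, with 0 unmatched value columns. Libraries were unstranded, so genes that overlap on opposite strands cannot be separated, and reads of close paralogs such as CCL3 and CCL3L, CCL4 and CCL4L, TPSAB1 and TPSB2 or HSPA1A and HSPA1B are divided between them with uncertainty.

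Estimated counts were rounded and tested with edgeR 4.0.16 (filterByExpr by group, TMM factors, robust quasi-likelihood fit and two-sided quasi-likelihood test), with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. Peripheral blood-derived libraries that share the first title number were summed, which gave 4 samples per treatment, and IL-33 number 3 has 1 library. Deviations from the group means of samples with the same first number correlated by 0.11 to 0.58, from the data and not from the labels. Tissue samples of different diagnoses that share a number also correlated (0.096 to 0.22), so a pairing by number is possible and not shown. The main fits did not use it, and a replicate block was an alternative. The difference of the IL-33 response was an interaction contrast in 1 fit over the genes in both tables. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were also used. What a replicate stands for (a person, a culture or a repeated library) is not given in the sources used here, so each p measures only the spread between these samples. The growth protocol text describes cord blood cultures, kept in SCF, IL-6 and IL-10, and gives none for peripheral blood-derived cells or for the isolation of tissue mast cells.

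The 27 gene lists were tested with limma's camera on edgeR log2 CPM (prior count 2) with a preset correlation of 0.01, for lists with at least 3 tested members and Benjamini-Hochberg adjustment within a comparison. Camera with an estimated correlation and fry were alternatives. Camera tests a list against the other genes, while fry tests it against no change, so a call by fry answers another question. Their subjects were mast cell identity, MCTC proteases and receptors, the IL-2 receptor and STAT5 pathway, cytokines and growth factors, chemokines, NF-kB targets and regulators, IL-33 receptor signalling, IgE receptor signalling and eicosanoid synthesis and receptors. Immediate early and AP-1 genes, heat shock genes, proliferation, interferon-stimulated genes, the unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, antigen presentation and co-stimulation and granule proteoglycan synthesis made up the next lists. The others were markers of T and NK cells, B and plasma cells, monocytes, macrophages and dendritic cells, epithelium, stroma and endothelium, eosinophils and basophils, neutrophils, and erythroid cells and megakaryocytes, and the mitochondrially encoded genes. In CRSwNP against CRSsNP the median and the test differed in sign for mast cell identity (0.0007, test lower), heat shock genes (-0.05, test higher), cholesterol synthesis (0.05, test lower) and erythroid and megakaryocyte markers (-0.17, test higher), none of which passed. Every list median was unchanged when genes with 0 to 3 reads in a group were placed at the bound that their counts allow. The sets of IL-33 response genes were not adjusted within a comparison. Their p were adjusted together over all 3 comparisons, separately for the preset and the estimated correlation.

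The groups, comparisons, gene lists, tests and the rule for naming genes were set before the data were examined. The rule names IL2RA, then, among genes with adjusted p under 0.05, an absolute log2 fold change of 1 or more, a mean log2 CPM above the median of tested genes and groups that do not overlap in CPM, the 10 of largest rise and the 10 of largest fall, and up to 4 members of smallest p from each list. For the difference of the IL-33 response it names the 5 largest positive and 5 largest negative differences, or, as no gene passed, the 10 of smallest p. EGR1 in peripheral blood-derived cells and DDIT4, DHCR7, ENO1, FYN, HPGDS, IRAK4, MAPK14, MYC, PGK1, PKM, PRG2, PTGDR2, PTGS1 and ZFP36 in cord blood-derived cells fall outside the rule and were named after their values were seen, to complete small counts. Genes whose level follows the donor rather than the group were neither tested nor named (sex-linked markers, common deletion genes, HLA-DRB and HLA-DQ genes, immunoglobulin and T cell receptor variable segments, CCL3L and CCL4L), which left out 1054, 1072 and 1054 genes of the tissue, peripheral and cord blood-derived tables. Some results that the rule covers are not reported here. Positions are from GENCODE v29. Ratios with 1 to 3 reads in a group carry exact 95% counting intervals, groups at 0 are set against a floor of 3 reads over the group, and intervals and floors cover counting error only.

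In a simulation on these libraries, with 200 genes changed, the tissue comparison recovered 7.46% of genes changed by a log2 fold change of 1, 65.7% at 2 and 92.4% at 4, with 9.76% false calls. Peripheral blood-derived cells gave 8.96%, 73.1% and 92.4% with 7.63% false calls, and cord blood-derived cells 44.8%, 91.0% and 95.5% with 11.1% false calls. The interaction contrast recovered 0%, 19.4% and 72.7% with 0 false calls. A shifted list was found by camera with the preset correlation in all 3 comparisons, and with an estimated correlation in tissue (adjusted p = 0.029) and peripheral blood-derived cells (adjusted p = 0.0054) but not in cord blood-derived cells (adjusted p = 0.17), while none of 20 unshifted lists was called. The simulated genes were drawn independently of each other, so these lists cannot show how camera behaves on correlated genes.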

Results

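Poly(A) RNA from human mast cells was measured by SmartSeq2 sequencing of lysates of 1000 cells. The 25 libraries came from nasal tissue, from cultures grown out of umbilical cord blood and from cultures grown out of adult peripheral blood. Tissue mast cells of the MCTC type, which store both tryptase and chymase, formed 3 samples from chronic rhinosinusitis with nasal polyps (CRSwNP) and 3 from chronic rhinosinusitis without nasal polyps (CRSsNP). All 6 tissue samples carry the tissue label nasal polyp, including those titled CRSsNP, and the labels do not resolve this. Cultured cells received saline or 10 ng/mL of the alarmin cytokine IL-33 for 4 h. Cord blood-derived cells gave 2 libraries per treatment. Peripheral blood-derived cells gave 8 saline and 7 IL-33 libraries, whose titles carry a first and a second number that no label explains, so libraries with the same first number were summed to 4 samples per treatment. Total estimated counts per library were 1598684 to 2987381 in CRSsNP, 1805016 to 2927834 in CRSwNP, 3282349 to 3371795 in cord blood saline and 3018984 to 3326814 in cord blood IL-33 libraries. Peripheral blood-derived libraries held 1127373 to 5613957 with saline and 1110627 to 5436577 with IL-33.

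The first comparison asked how mast cells of polyps differ from those of rhinosinusitis without polyps, with CD25, the alpha chain of the IL-2 receptor, at its centre because the series title names it. IL2RA (10:6010689-6062370, minus strand, GRCh38) encodes CD25 and was higher in CRSwNP mast cells, at 66.3 ± 29.2 TPM (transcript abundance scaled to gene length and library; SD, n = 3) against 2.14 ± 1.66 TPM in CRSsNP. This was a log2 fold change of 4.89 ± 0.58 (SE; adjusted p = 0.00515), from 740 of 7477722 reads against 25 of 7054229, and all 3 CRSwNP samples lay above all 3 CRSsNP samples. IL10RA (11:117986348-118003037, plus strand), the receptor chain through which IL-10 signals, was higher by 6.27 ± 0.81 (adjusted p = 0.019). IL9R, the receptor for the mast cell growth factor IL-9, was higher by 3.54 ± 0.52 (adjusted p = 0.015), so 3 cytokine receptor chains were among the genes of largest increase. SLC40A1 (2:189560579-189583758, minus strand), which encodes the iron exporter ferroportin, was the gene of largest decrease among those the naming rule covers, with a log2 fold change of -5.01 ± 0.41 (adjusted p = 7.4e-05) and 5.96 ± 3.71 CPM (counts scaled to library size; SD, n = 3) against 203 ± 30.4.

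**Figure D1:**
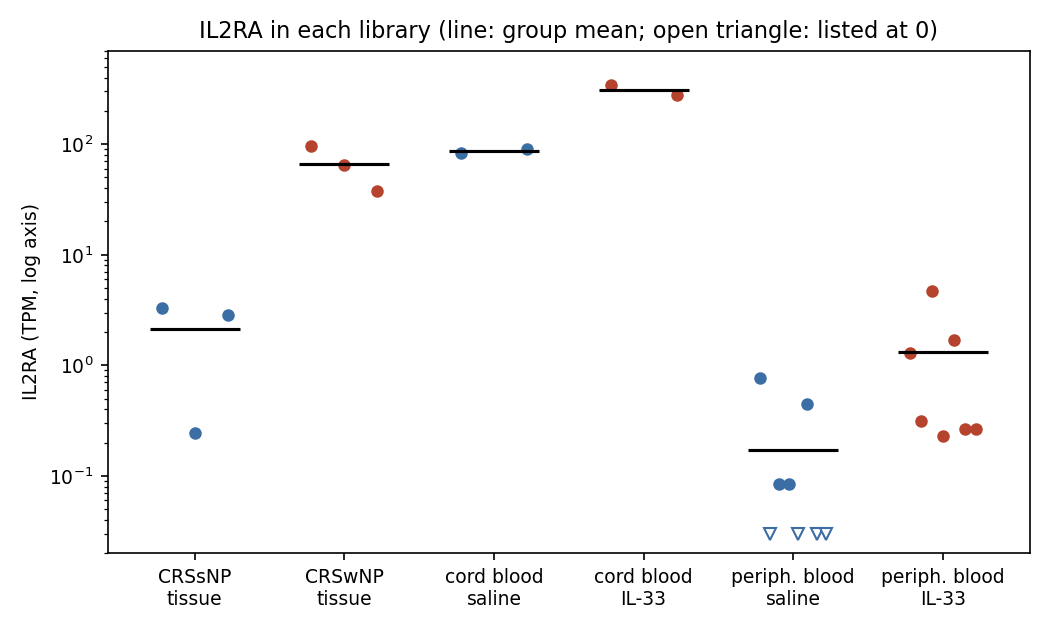
IL2RA in TPM, on a log axis, for each of the 25 libraries by group, with a line at the group mean and open triangles for libraries listed at 0. CRSwNP libraries lie between 37.6 and 95.9 TPM and CRSsNP libraries between 0.242 and 3.30 TPM, and cord blood-derived cells rise from 83.7 to 90.1 TPM with saline to 279 to 345 TPM with IL-33.

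Of 12207 genes tested with edgeR, 59 were higher and 36 lower in CRSwNP at adjusted p under 0.05, against 1004 genes at an unadjusted p under 0.05, and leaving out 1 replicate gave 49 to 92 genes. Of the 95 calls, 50 were kept in the same direction with transcript length offsets and 38 with limma-trend, against 95 with DESeq2. PHLDA1, a stress-responsive regulator of growth factor signalling, was higher by 3.94 ± 0.34 (adjusted p = 7.4e-05). TRAF1, an adapter of tumour necrosis factor receptors and itself an NF-kB target, was higher by 3.44 ± 0.42 (adjusted p = 0.0013). The remaining genes of largest increase under the naming rule were MLC1, OSBPL6, the granule protease gene CTSW, which cytotoxic T and NK cells also express, and the ion channel genes TMEM176B and TMEM176A, with log2 fold changes between 2.70 and 4.39. PLAT and PLAU, which encode the plasminogen activators tPA and uPA, were lower by log2 fold changes of -3.20 ± 0.29 (adjusted p = 9.7e-05) and -1.99 ± 0.25 (adjusted p = 0.0017). GFRA1, MSRB3, ABI3BP, BSPRY, CAVIN2, SLCO2B1 and SPTBN1 completed the 10 largest decreases under this rule, with log2 fold changes from -3.68 for GFRA1 to -1.88 for SPTBN1. Adjusted p reached 0.041 for GFRA1 and 0.020 for SPTBN1. Besides IL2RA, which kept its call in each of the 6 fits without a replicate, 31 genes named here or below passed in this comparison. Of these 31 genes, 17 lost their call in at least 1 of the 6 fits, among them IL10RA, MLC1, IL9R and GFRA1, while PHLDA1, TRAF1, SLC40A1, PLAT and PLAU kept theirs.

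**Figure D2:**
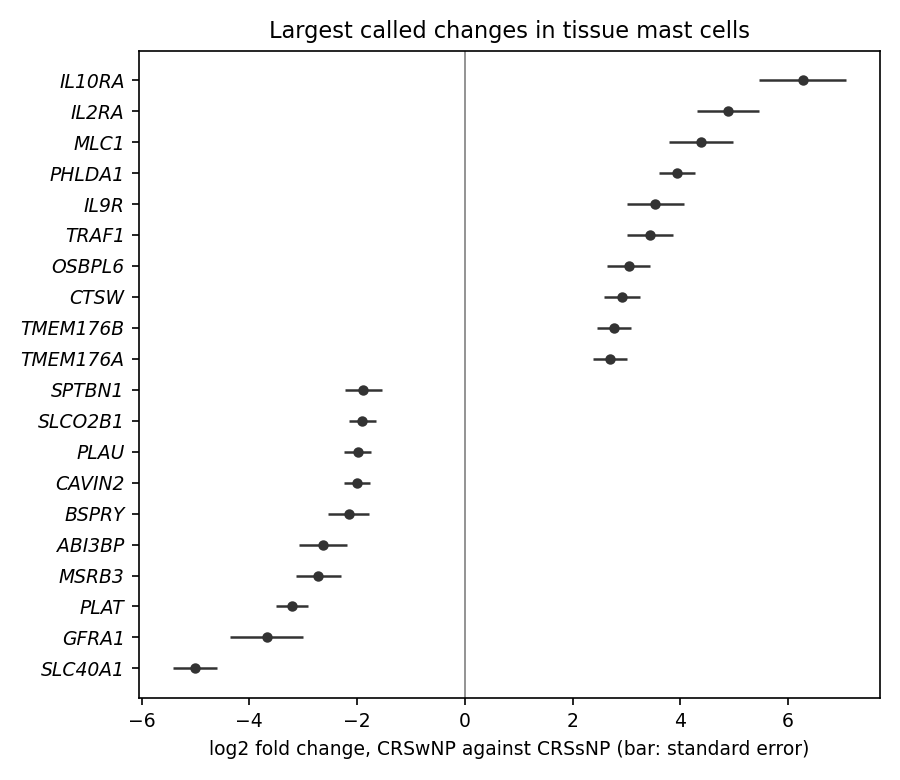
Log2 fold change of CRSwNP over CRSsNP mast cells (n = 3 and 3) for the 10 genes of largest increase and the 10 of largest decrease among those that the naming rule covers by level and lack of overlap, with bars of 1 SE. Values run from -5.01 for SLC40A1 to 6.27 for IL10RA.

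IL3, which encodes a growth factor for mast cells and basophils, had 154 reads in CRSwNP against 3 in CRSsNP, a ratio of 48.3 with a 95% counting interval of 16.2 to 237 (adjusted p = 0.0053). OSM, an IL-6 family cytokine and STAT5 target, was higher by 1.95 ± 0.33 (adjusted p = 0.015), and its relative LIF by 1.54 ± 0.27 (adjusted p = 0.016). AREG, an epidermal growth factor receptor ligand, did not pass (1.19 ± 0.30, adjusted p = 0.10). In the cytokine and growth factor list, 3 of 17 tested members were higher over all genes and 7 when adjusted over the list alone, and the list test gave adjusted p = 0.0026. With an estimated correlation this was adjusted p = 0.47, and with fry adjusted p = 0.13. In the IL-2 receptor and STAT5 list, IL2RA, OSM and SOCS2, a STAT5-induced feedback inhibitor (1.97 ± 0.36), were the 3 of 17 members past the threshold, with 7 adjusted over the list alone. That list had a median log2 fold change of 0.57 and adjusted p = 5.0e-04, and adjusted p = 0.67 with an estimated correlation. PIM1, a kinase downstream of STAT5, was higher by 2.83 ± 0.52 without passing (adjusted p = 0.055).

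The NF-kB list had TRAF1 and MAP3K8, a kinase upstream of ERK (1.90 ± 0.33), as the 2 of 32 members past the threshold, with 7 higher and 1 lower adjusted over the list alone. Its test gave adjusted p = 5.0e-04, and adjusted p = 0.67 with an estimated correlation. NFKBID (1.199 ± 0.31, adjusted p = 0.12) and ZC3H12A (2.37 ± 0.54, adjusted p = 0.16) did not pass. The mitochondrially encoded list was shifted higher as a set (adjusted p = 1.4e-04, and adjusted p = 0.71 with an estimated correlation), although none of its 13 members passed in edgeR and 3 did adjusted over the list alone. Its member MT-ND4 did not pass (0.92 ± 0.30, adjusted p = 0.30). Epithelial markers were shifted lower (adjusted p = 0.0038, and adjusted p = 0.47 with an estimated correlation), with 0 of 6 tested members past the threshold and 3 adjusted over the list alone. Among them were KRT8 (-1.61 ± 0.41, adjusted p = 0.11), KRT19 (-0.84 ± 0.29, adjusted p = 0.34) and PIGR (-2.10 ± 0.77, adjusted p = 0.39).

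Mast cell identity genes showed no list call (0 of 28 members, 0 adjusted over the list alone, adjusted p = 0.845). Neither did the MCTC protease and receptor list (0 of 6, with 1 higher and 1 lower adjusted over the list alone, adjusted p = 0.688). Within them MRGPRX2, the receptor for basic secretagogues, had 6.99 ± 2.79 CPM in CRSwNP against 111 ± 95.4 in CRSsNP, a log2 fold change of -3.998 ± 1.07 that did not pass (adjusted p = 0.36). It passed without CRSsNP replicate 1, at -4.51 (adjusted p = 2.7e-04). Chymase, encoded by CMA1 (-1.29 ± 0.60, adjusted p = 0.68), FCER1A (0.94 ± 0.31, adjusted p = 0.31) and LTC4S (0.91 ± 0.32, adjusted p = 0.36) did not pass either.

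In the IgE receptor signalling list GAB2, an adapter of Fc epsilon receptor signalling, was the 1 of 22 members past the threshold, higher by 2.05 ± 0.30 (adjusted p = 0.0051), with 4 higher and 2 lower adjusted over the list alone and a list adjusted p of 0.190. LYN, the kinase that starts this cascade, did not pass (-1.05 ± 0.31, adjusted p = 0.23). Single members also passed in 3 other lists without a list call. These were AURKA, higher by 2.07 ± 0.43, in proliferation (1 of 15, 1 adjusted over the list alone, list adjusted p = 0.845), CHST15, higher by 3.55 ± 0.69, in granule proteoglycan synthesis (1 of 17, 1 higher and 2 lower adjusted over the list alone, list adjusted p = 0.389) and P2RY14, higher by 1.49 ± 0.27, in eosinophil and basophil markers (1 of 6, 1 adjusted over the list alone, list adjusted p = 0.288). B and plasma cell markers had 0 of 4 members past the threshold and 2 lower adjusted over the list alone (list adjusted p = 0.190). These were IGHA1, at -4.15 ± 1.11 (adjusted p = 0.24), and IGKC, at -4.14 ± 1.21 (adjusted p = 0.38).

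The remaining lists had 0 members past the threshold in edgeR. Immediate early and AP-1 genes had 2 higher and 3 lower adjusted over the list alone (list adjusted p = 0.630), and erythroid and megakaryocyte markers had 1 higher (list adjusted p = 0.604). With 0 adjusted over the list alone, the list adjusted p was 0.282 for chemokines, 0.866 for IL-33 receptor signalling, 0.389 for eicosanoid genes, 0.866 for heat shock genes, 0.539 for interferon-stimulated genes, 0.195 for the unfolded protein response, 0.845 for cholesterol synthesis, 0.288 for glycolysis and hypoxia and 0.639 for antigen presentation. It was 0.845 for T and NK cell markers, 0.644 for monocyte, macrophage and dendritic markers, 0.886 for stromal and endothelial markers and 0.389 for neutrophil markers.

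The second comparison asked what IL-33 changes in peripheral blood-derived MCTC. IL13, the type 2 cytokine gene (5:132656263-132661110, plus strand), went from 2 reads with saline to 2001 with IL-33, a ratio of 1482 with a 95% counting interval of 410 to 12243 (adjusted p = 2.8e-04, n = 4 and 4, edgeR). PTX3 (3:157436789-157443628, plus strand), a secreted pattern recognition molecule, went from 2 to 852 reads, a ratio of 631 (174 to 5218), and CSF2, which encodes GM-CSF, from 3 to 878 reads, a ratio of 433 (148 to 2106). BIRC3, an NF-kB-induced inhibitor of apoptosis, rose by a log2 fold change of 7.77 ± 0.58 (adjusted p = 1.1e-04). In the opposite direction THSD1 (13:52377167-52416373, minus strand), a membrane protein gene, fell by 4.53 ± 0.52, IFIT2, an interferon-induced gene, by 3.42 ± 0.29, and IL16, a chemoattractant for CD4-bearing cells, by 3.12 ± 0.35 (adjusted p = 8.8e-04, 1.6e-04 and 8.8e-04).

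Of 12780 genes tested, 288 rose and 108 fell at adjusted p under 0.05, against 1669 at an unadjusted p under 0.05. Leaving out 1 number from a group moved the 396 to between 193 and 658. With the first title number as a replicate block, 406 rose and 207 fell. The other genes of largest rise among those the naming rule covers were CCL4 (9.89 ± 1.88, adjusted p = 0.016), SDC4 (7.65 ± 0.85), IRF4 (7.63 ± 0.64), CCL1 (7.15 ± 0.66), C15orf48 (6.99 ± 0.65) and TRAF1 (5.83 ± 0.72). Reads of CCL4 can be shared with its CCL4L paralogs, and the CCL4 call was lost without saline number 1, 2, 3 or 4 or IL-33 number 2. The size of its rise rests largely on IL-33 number 3, at 504 CPM against 4.25 to 36.5 CPM in the other IL-33 samples. The other such genes of largest fall were MIDEAS, INKA1, ZMYND8, HS3ST1, LPAR5, MC1R and TAL1, with log2 fold changes from -2.73 for MIDEAS to -2.01 for TAL1. MC1R overlaps a readthrough transcript, which unstranded reads cannot separate from it. Besides TNFRSF1B and CD200R1, which are named for the difference of the IL-33 response, 60 genes named here or below passed in these cells. Of these 60, 19 lost their call in at least 1 of the 8 fits without a number. VEGFA and KLF10 lost it in 7, MC1R, IRAK2, DNAJA1, GNAI1, RRP1B and KLF7 in 6, CD40, IFIT1 and DDIT4 in 5, HSPA6 and EGR1 in 4, and PFKFB3 and SDF2L1 in 3.

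IL2RA was too low for the gene-wide test in these cells. It had 4 of 33445918 reads with saline and 39 of 22644834 with IL-33, a ratio of 14.4 with a 95% counting interval of 5.197 to 55.5. Of the 39 reads 20 came from 1 library, and without it, an alternative chosen after seeing the data, the ratio was 9.23 (3.07 to 37.3). All 4 IL-33 samples lay above all 4 saline samples (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 can give). Between samples of the same first number all 4 differences were positive, and a test that keeps these pairs did not reach the threshold (exact permutation test of signs, two-sided p = 0.125, the smallest that 4 pairs can give). Mean abundance was 1.31 ± 0.97 TPM with IL-33 and 0.173 ± 0.167 TPM with saline (SD, n = 4).

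NF-kB genes moved as a set, with 29 of 33 tested members higher and 31 adjusted over the list alone. The list test gave adjusted p = 1.2e-44, and adjusted p = 0.034 with an estimated correlation. REL, NFKBIA and NFKB1, which encode NF-kB subunits and their inhibitor, rose by 4.18 ± 0.30, 4.15 ± 0.30 and 3.61 ± 0.28. Cytokine and growth factor genes rose too, with 9 of 16 members higher, 10 higher and 1 lower adjusted over the list alone, and a list adjusted p of 5.0e-12 (adjusted p = 0.032 with an estimated correlation). IL10 rose by 4.29 ± 0.49, and EBI3, a subunit of IL-27 and IL-35, had 390 reads against 1, a ratio of 578 (103 to 22870). The 5 of 9 chemokine genes past the threshold were CCL1, CCL4, CXCL2, CXCL3 and CXCL8, with 6 adjusted over the list alone, and the list had adjusted p = 1.6e-09 (adjusted p = 0.032 with an estimated correlation). Without 4 libraries that stand apart on the first principal component, an alternative chosen after seeing the data, none of these 3 lists passed with an estimated correlation (adjusted p = 0.0799 for each), and all 3 passed with the preset one. CXCL8 and CXCL2, which attract neutrophils, had 0 saline reads, and their IL-33 reads were at least 147-fold and at least 157-fold higher against a floor of 3 reads over the group. CXCL3 rose by 6.77 ± 0.70.

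Further lists passed with the preset correlation and not with an estimated one. Immediate early and AP-1 genes had 11 of 23 members higher and 1 lower, with 16 and 3 adjusted over the list alone (adjusted p = 3.3e-12, and adjusted p = 0.056 with an estimated correlation). BATF, an AP-1 factor, rose by 2.79 ± 0.22, DUSP5 by 3.62 ± 0.44, FOSB by 3.56 ± 0.49 and IER5 by 3.19 ± 0.39, while EGR1, named after its value was seen as the 1 lower member, fell by 2.09 ± 0.42. Heat shock genes had HSPA6 (4.05 ± 0.81), DNAJB4 (1.75 ± 0.27) and DNAJA1 (1.13 ± 0.26) as the 3 of 14 higher members, 5 adjusted over the list alone, and adjusted p = 5.1e-06 (adjusted p = 0.052 with an estimated correlation). In the IL-2 receptor and STAT5 list PIM1 (3.41 ± 0.47), SOCS2 (2.34 ± 0.27) and PIM2 (1.61 ± 0.28) were the 3 of 15 higher members, 8 adjusted over the list alone, with adjusted p = 2.1e-05 (adjusted p = 0.42 with an estimated correlation). Cholesterol synthesis had INSIG1 (2.48 ± 0.24) and HMGCS1 (2.19 ± 0.27) as the 2 of 19 higher members, 4 adjusted over the list alone, and adjusted p = 0.0014 (adjusted p = 0.53 with an estimated correlation). SQLE, a later enzyme of that pathway, did not pass (0.77 ± 0.19, adjusted p = 0.053).

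Antigen presentation and co-stimulation had CD274, which encodes PD-L1 (2.83 ± 0.39), and CD40 (3.29 ± 0.65) as the 2 of 11 higher members, 3 adjusted over the list alone, with adjusted p = 0.025 (adjusted p = 0.14 with an estimated correlation). Proliferation genes were shifted lower, with 0 of 24 members past the threshold and 0 adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.53 with an estimated correlation). Granule proteoglycan synthesis was also shifted lower, with HS3ST1, a heparan sulfate sulfotransferase gene (-2.12 ± 0.39), as the 1 of 15 lower members and 1 adjusted over the list alone (adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation). Without the 4 libraries its median went from -0.263 to -0.024 and it no longer passed (adjusted p = 0.325).

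Other lists gave no list call. Mast cell identity had 0 of 28 members past the threshold, 2 higher and 1 lower adjusted over the list alone (list adjusted p = 0.171). GATA2 (1.17 ± 0.31, adjusted p = 0.086), MITF (-1.10 ± 0.31, adjusted p = 0.11), IL1RL1, the IL-33 receptor gene (0.87 ± 0.25, adjusted p = 0.12), and MRGPRX2 (-1.07 ± 0.34, adjusted p = 0.16) did not pass. With the block GATA2, MITF and MRGPRX2 passed (adjusted p = 0.022, 0.010 and 0.028). C3AR1, the receptor for complement C3a, fell by 2.01 ± 0.33 (adjusted p = 0.0074) in the MCTC protease and receptor list, as the 1 of 6 lower members with 2 adjusted over the list alone (list adjusted p = 0.0703). IL-33 receptor signalling had IRAK2 (3.28 ± 0.68) and TAB2 (1.68 ± 0.23) as the 2 of 17 higher members, 4 adjusted over the list alone (list adjusted p = 0.337). PTGS2, which encodes cyclooxygenase 2, rose by 4.78 ± 0.37 (adjusted p = 1.1e-04) as the 1 of 17 eicosanoid genes past the threshold, 1 adjusted over the list alone (list adjusted p = 0.867). Interferon-stimulated genes had IFIT2, IFIT1 (-2.47 ± 0.47) and IFIT3 (-1.78 ± 0.29) as the 3 of 20 lower members, 3 adjusted over the list alone (list adjusted p = 0.206), where the median was 0.08 while the test pointed lower. Without the 4 libraries this list passed as lower (adjusted p = 0.0336).

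In the unfolded protein response list SDF2L1 rose by 1.17 ± 0.20 and DDIT4 fell by 1.72 ± 0.33 (1 and 1 of 20, the same numbers adjusted over the list alone, list adjusted p = 0.248). PFKFB3 (3.46 ± 0.62) and VEGFA (2.05 ± 0.45) rose in the glycolysis and hypoxia list (2 of 21, with 3 higher and 2 lower adjusted over the list alone, list adjusted p = 0.618). IL7R, listed with T and NK cell markers, rose by 2.75 ± 0.40 (1 of 5, 1 adjusted over the list alone, list adjusted p = 0.202). Lists with 0 members past the threshold had list adjusted p of 0.202 for IgE receptor signalling, 0.945 for monocyte, macrophage and dendritic markers, 0.945 for epithelial markers, 0.867 for stromal and endothelial markers, 0.966 for eosinophil and basophil markers and 0.645 for mitochondrially encoded genes. Adjusted over the list alone these had 0 members, except 1 lower eosinophil and basophil marker. B and plasma cell, neutrophil and erythroid markers had 2, 0 and 1 tested members, too few to test.

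**Figure D3:**
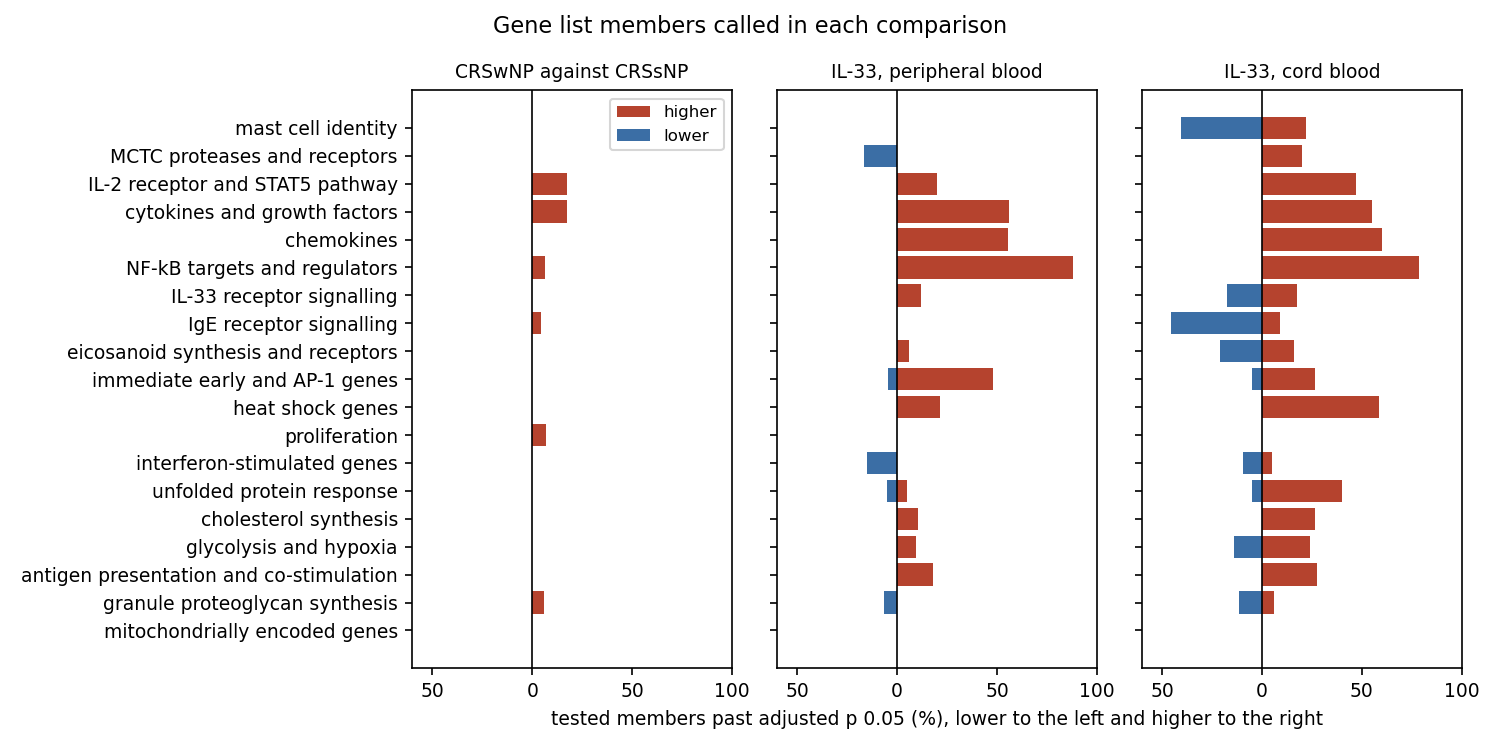
Percent of tested members of 19 gene lists past adjusted p 0.05 in each of the 3 comparisons, with higher members to the right and lower members to the left of 0. NF-kB genes reach 29 of 33 in peripheral blood-derived cells, 26 of 33 in cord blood-derived cells and 2 of 32 in CRSwNP against CRSsNP.

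The third comparison asked the same of cord blood-derived mast cells. With saline, 46 markers of neutrophils, monocytes and eosinophils or basophils summed to 12783 TPM here, against 662 TPM in peripheral blood-derived cells. Which cells of these cultures gave the response below can therefore not be told. IL2RA, at 86.9 ± 4.50 TPM with saline, rose to 312 ± 46.4 TPM with IL-33 (SD, n = 2), a log2 fold change of 1.89 ± 0.10 (adjusted p = 1.8e-06) with both IL-33 libraries above both saline libraries. IL5 (5:132541444-132556838, minus strand), the eosinophil growth factor gene, had 0 saline and 1095 IL-33 reads, at least 382-fold higher against a floor of 3 reads over the group. CCR7 (17:40553769-40565472, minus strand), a homing receptor for lymphoid tissue, rose by 6.64 ± 0.22. RHEX (1:206052723-206102459, plus strand), a regulator of erythropoietin signalling, fell by 3.10 ± 0.14, and MITF, a transcription factor of mast cell differentiation, fell by 1.99 ± 0.15.

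Of 11679 genes tested with edgeR, 890 rose and 629 fell at adjusted p under 0.05, and 412 rose and 314 fell by a log2 fold change of at least 1. MAOA, a monoamine oxidase gene, rose by 5.68 ± 0.49 (adjusted p = 0.0076), BIRC3 by 5.29 ± 0.13 and TRAF1 by 4.78 ± 0.17. EBI3, SDC4, SSTR2 and TNFRSF9 were also among the genes of largest increase under the naming rule, with log2 fold changes between 3.63 and 4.40. SLC40A1 fell here as well, by 2.17 ± 0.20. PLXNA2, DRD2, CROT, GNAI1, SPTBN1, TGFBR2, PPM1H and MITF had the other large decreases among genes that the naming rule covers by level and lack of overlap. Their log2 fold changes ran from -2.50 to -1.99. With 2 libraries per group these 1519 calls rest on 2 residual degrees of freedom. The biological coefficient of variation was 13.1%, against 35.1% in tissue and 38.7% in peripheral blood-derived cells. Whether the 2 libraries are separate cultures is not given, so more calls here need not mean a broader response. Of the 1519 calls, 914 were kept in the same direction with DESeq2, 718 with transcript length offsets and 552 with limma-trend. Besides IL2RA, and C15orf48, CD69 and REL, which are named for the difference of the IL-33 response, 99 genes named here or below passed. Some of them lost their call in fits without a library, which leave 1 sample in a group.

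NF-kB genes were again the list with most members higher, 26 of 33, and 29 adjusted over the list alone (adjusted p = 2.2e-22, and adjusted p = 0.29 with an estimated correlation). ICAM1, an adhesion molecule, rose by 2.61 ± 0.11. Cytokine genes had 11 of 20 members higher, 13 higher and 2 lower adjusted over the list alone (adjusted p = 7.7e-08, and adjusted p = 0.29 with an estimated correlation), among them IL1B (2.30 ± 0.12) and TNFSF10, which encodes the death ligand TRAIL (1.58 ± 0.11). Chemokine genes had 9 of 15 members higher, 11 adjusted over the list alone (adjusted p = 7.7e-08, and adjusted p = 0.35 with an estimated correlation), with CXCL3 at 3.65 ± 0.28, CCL4 at 2.46 ± 0.11, CXCL8 at 1.83 ± 0.11 and CCL3 at 1.61 ± 0.14. In the IL-2 receptor and STAT5 list 8 of 17 members were higher, 8 adjusted over the list alone (adjusted p = 2.3e-05, and adjusted p = 0.29 with an estimated correlation), including PIM2 (2.91 ± 0.12), STAT5A (1.98 ± 0.16) and the survival gene BCL2L1 (1.97 ± 0.12).

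The unfolded protein response had 8 of 20 members higher and 1 lower, with 10 and 1 adjusted over the list alone (adjusted p = 5.4e-05, and adjusted p = 0.29 with an estimated correlation). CHAC1 rose by 2.44 ± 0.29, HERPUD1 by 1.22 ± 0.12 and the chaperone gene HSPA5 by 0.88 ± 0.10, while DDIT4 fell by 0.56 ± 0.11. Heat shock genes had 7 of 12 members higher, 7 adjusted over the list alone (adjusted p = 4.1e-04, and adjusted p = 0.29 with an estimated correlation), with DNAJA1 at 0.82 ± 0.10. Cholesterol synthesis had HMGCS1 (1.28 ± 0.18), SQLE (0.93 ± 0.12), MVD (0.90 ± 0.13), MSMO1 (0.59 ± 0.12) and DHCR7 (0.56 ± 0.15) as the 5 of 19 higher members, 6 adjusted over the list alone (adjusted p = 0.0060, and adjusted p = 0.52 with an estimated correlation and 0.17 with fry). Antigen presentation had CD274 (2.45 ± 0.28), CD40 (1.53 ± 0.25) and CD74 (0.42 ± 0.12) as the 3 of 11 higher members, 5 adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.35 with an estimated correlation and 0.078 with fry). Granule proteoglycan synthesis was shifted lower, with HS3ST1 (-1.11 ± 0.11) and GLCE (-0.96 ± 0.27) lower and the core protein gene SRGN (0.74 ± 0.09) higher among 17 members, 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.0060, and adjusted p = 0.35 with an estimated correlation).

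Mast cell identity genes moved both ways without a list call in camera, with 6 of 27 higher and 11 lower, 10 and 11 adjusted over the list alone (list adjusted p = 0.296, and adjusted p = 0.033 with fry as a lower list). IL1RL1 rose by 1.58 ± 0.12, and the solute carrier gene SLC45A3 fell by 1.95 ± 0.12. CMA1 rose by 0.79 ± 0.11, the 1 of 5 MCTC protease and receptor genes past the threshold, 1 adjusted over the list alone (list adjusted p = 0.955). IgE receptor signalling had 10 of 22 members lower and 2 higher, 11 and 3 adjusted over the list alone (list adjusted p = 0.0613, and adjusted p = 0.028 with fry), with GRAP2 at -1.58 ± 0.14, INPP5D at -1.44 ± 0.16 and BTK at -1.18 ± 0.09, and GAB2 (1.38 ± 0.18) and FYN (0.73 ± 0.20) higher. IL-33 receptor signalling had IRAK2 (1.93 ± 0.23), IL1RL1 and TAB2 (1.32 ± 0.23) higher and MAPK14 (-0.84 ± 0.20), IRAK4 (-0.65 ± 0.19) and MYD88 (-0.46 ± 0.10) lower among 17 members, 5 and 3 adjusted over the list alone (list adjusted p = 0.537).

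Eicosanoid genes had PTGS2 (1.91 ± 0.11), PTGIR (1.86 ± 0.19) and PLA2G4A (1.59 ± 0.12) higher and PTGDR2 (-2.39 ± 0.40), ALOX5 (-1.63 ± 0.14), PTGS1 (-0.70 ± 0.11) and HPGDS (-0.55 ± 0.09) lower among 19 members, 5 and 4 adjusted over the list alone (list adjusted p = 0.993). Immediate early genes had BATF (3.33 ± 0.13), EGR2 (1.65 ± 0.27), DUSP4 (1.49 ± 0.13), BTG2 (1.35 ± 0.10) and MYC (0.86 ± 0.17) higher and ZFP36 (-0.77 ± 0.21) lower among 19 members, 6 and 2 adjusted over the list alone (list adjusted p = 0.134). Eosinophil and basophil markers had IL3RA (3.21 ± 0.12) and PRG2 (0.42 ± 0.09) higher and P2RY14 (-2.47 ± 0.25), IL5RA (-1.19 ± 0.23) and SIGLEC8 (-0.66 ± 0.13) lower among 11 members, 2 and 5 adjusted over the list alone (list adjusted p = 0.670). In the glycolysis and hypoxia list 8 of 21 members passed in either direction, 8 adjusted over the list alone (list adjusted p = 0.5683), with ADM (1.27 ± 0.17), PFKP (0.56 ± 0.11), ENO1 (0.37 ± 0.08), PKM (0.36 ± 0.09) and PGK1 (0.32 ± 0.09) higher and SLC2A3 (-1.18 ± 0.12) and HK1 (-0.56 ± 0.10) among the lower ones.

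Interferon-stimulated genes had GBP2 (1.09 ± 0.12) higher and RSAD2 (-1.78 ± 0.21) and IFIT2 (-1.29 ± 0.35) lower among 21 members, 1 and 2 adjusted over the list alone (list adjusted p = 0.272). IL7R (1.86 ± 0.16) and CCL5 (1.49 ± 0.38) were the 2 of 4 T and NK cell markers higher, 2 adjusted over the list alone (list adjusted p = 0.0584, and adjusted p = 0.033 with fry). DEFA3 (2.27 ± 0.55) was the 1 of 10 neutrophil markers past the threshold, 1 adjusted over the list alone (list adjusted p = 0.543). LUM (0.92 ± 0.25) and PECAM1 (-0.81 ± 0.22) were the stromal and endothelial markers past the threshold among 7, 1 higher and 1 lower adjusted over the list alone (list adjusted p = 0.956). No member passed over all genes in the other lists, whose list adjusted p was 0.380 for proliferation, 0.986 for B and plasma cell markers, 0.696 for monocyte, macrophage and dendritic markers, 0.986 for epithelial markers, 0.696 for erythroid markers and 0.134 for mitochondrially encoded genes. Adjusted over the list alone these had 0 members, except 1 higher and 1 lower epithelial marker.

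The fourth comparison asked whether the IL-33 response differed between both kinds of cultured cells. Induced genes were shared to a large degree, with 163 genes higher in both where 19.95 were expected by chance among 10688 genes tested in both, and 51 lower in both where 5.61 were expected (Fisher's exact test, p = 9.6e-119 and 1.8e-37). KLF10 and KLF7, named after their values were seen, were the 2 genes that changed in opposite directions. Of the genes higher in peripheral blood-derived cells by a log2 fold change of at least 1, 251 were tested in cord blood-derived cells, where 94.8% had a positive log2 fold change against 48.7% of all genes. Their median was 1.22 and 159 were higher and 1 lower past the threshold (list adjusted p = 7.3e-46, and adjusted p = 0.0267 with an estimated correlation). Genes lower in peripheral blood-derived cells had a median of -0.84 in cord blood-derived cells, with 48 of 95 lower past the threshold (adjusted p = 0.0299 with an estimated correlation).

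**Figure D4:**
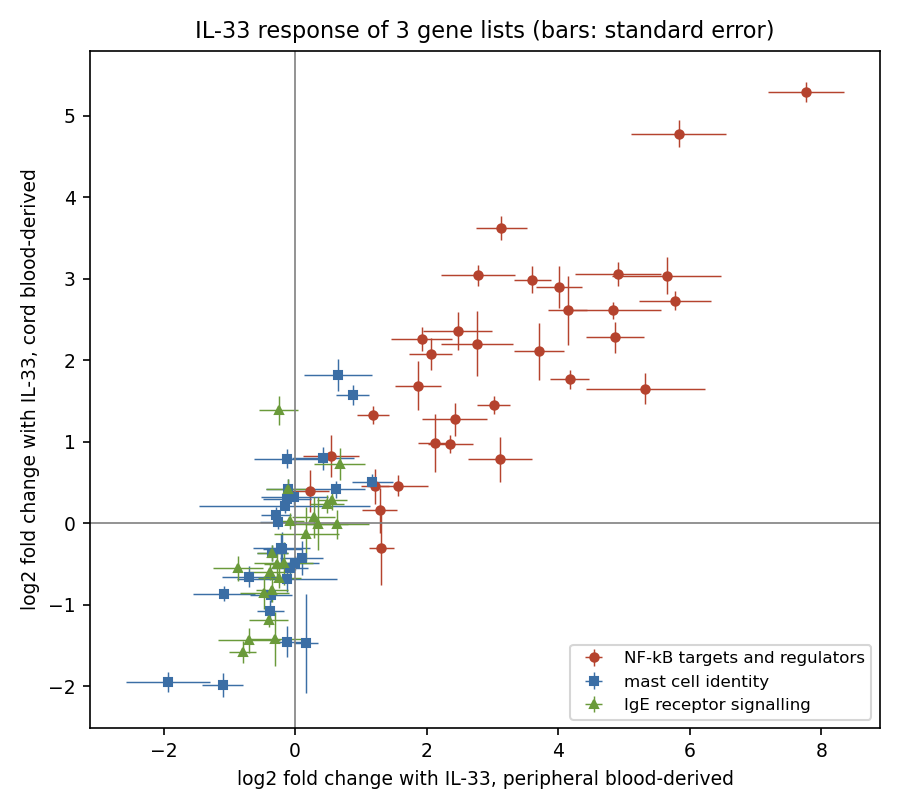
Log2 fold change with IL-33 in peripheral blood-derived cells (horizontal axis, n = 4 and 4) and cord blood-derived cells (vertical axis, n = 2 and 2) for members of the NF-kB, mast cell identity and IgE receptor signalling lists, with bars of 1 SE. Among NF-kB genes 31 of 32 lie above 0 on both axes, and 12 of 27 mast cell identity genes lie below 0 on both.

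For the difference itself, 0 of 13213 genes passed in edgeR, with 615 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0849. With the replicate block 14 genes passed, among them C15orf48, TNFRSF1B, SLC40A1, CXCL8, CXCL2, REL and PTGS2, and without IL-33 number 2 of the peripheral blood-derived cells 44 passed. No other tool was run for this contrast. The genes of smallest p, none of which passed without the block, differed by 3.94 ± 0.61 for TNFRSF1B, 5.12 ± 0.81 for C15orf48, 2.31 ± 0.38 for SLC40A1 and -2.54 ± 0.42 for IL3RA, as peripheral minus cord blood-derived log2 fold change. CXCL8 and CXCL2 had 0 saline reads in peripheral blood-derived cells, so no fold is given for their difference (adjusted p = 0.0849 for each). SLC40A1 had a log2 fold change of 0.15 in peripheral and -2.17 in cord blood-derived cells, and IL3RA of 0.71 and 3.21. Neither passed in peripheral blood-derived cells (edgeR, adjusted p = 0.82 for SLC40A1 and 0.56 for IL3RA). CD69 (-2.21 ± 0.38), REL (2.40 ± 0.42), CD200R1 (-2.20 ± 0.38) and PTGS2 (2.86 ± 0.50) had adjusted p = 0.0955. IL2RA differed by 1.70 ± 0.72 (adjusted p = 1.00).

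The last comparison asked whether genes that IL-33 induced in culture were higher in CRSwNP than in CRSsNP mast cells. TRAF1, MAP3K8 and SOCS2 were among the genes higher in CRSwNP and with IL-33 in both kinds of cultured cells. With peripheral blood-derived cells 5 higher genes were shared where 1.09 were expected (Fisher's exact test, p = 0.0045). With cord blood-derived cells 13 higher genes were shared where 3.79 were expected (Fisher's exact test, p = 6.5e-05), including IL2RA, TRAF1, GAB2, SOCS2, MAP3K8, TMEM176A and TMEM176B. Which cells of the cord blood-derived cultures gave these genes cannot be told. SLC40A1, GNAI1 and SPTBN1 were among the 5 lower genes shared with cord blood-derived cells (1.55 expected, Fisher's exact test, p = 0.018). IL9R, P2RY14 and PLAU were among 10 genes that went opposite ways in CRSwNP and with IL-33 in cord blood-derived cells. No expected number was computed for these, so how far the sharing depends on direction was not tested. Fisher's test also treats genes as independent, which genes regulated together are not. MAP3K8, SOCS2 and SPTBN1 lost their tissue call in some of the fits without a replicate. GNAI1, RRP1B and ST3GAL6 were the 3 lower genes shared with peripheral blood-derived cells (0.274 expected, Fisher's exact test, p = 0.0025), and each lost its tissue call in 5 or 6 of the 6 fits without a replicate. Genes in these shared sets that no other part names were named after their values were seen.

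As a set, the 232 tested genes higher with IL-33 in peripheral blood-derived cells had a median log2 fold change of 0.12 in CRSwNP, and 60.3% of them were positive against 48.1% of all tested genes (adjusted p = 8.1e-04). With an estimated correlation this was adjusted p = 0.27. Without CRSsNP replicate 1 the median was 0.13 and the set no longer passed. Genes lower with IL-33 in peripheral blood-derived cells gave adjusted p = 0.0914. The set from cord blood-derived cells did not pass (333 genes tested, median 0.03, adjusted p = 0.160 for higher genes and 0.430 for lower genes). Its top 100 genes by p had an unadjusted camera p of 2.9e-05 (89 tested, median 0.30). The set without CRSsNP replicate 2 had an unadjusted camera p of 0.026 (median 0.08).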

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

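The test of whether 4 libraries give the IL-33 calls was chosen after the result was seen, and their removal as an alternative was chosen after seeing the data. Outliers were sought in peripheral blood-derived cells only, in 144 groups of values. These were groups of 4 samples for named genes, and of 8 saline or 7 IL-33 libraries for library measures. In 9 of them a sample's gap to its nearest neighbour was a larger share of the group's range than Dixon's 95% critical value. Chance alone marks about 1 in 20 groups.

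Among the 4 IL-33 samples of peripheral blood-derived cells, CCL4 was high in number 3, at 504 CPM against 4.25 to 36.5, a gap of 0.935 of the range. IER5 was also high in number 3 (19.7 against 12.4 to 13.4 CPM, 0.858). HMGCS1 was high in number 4 (499 against 242 to 275 CPM, 0.871). IL7R and DNAJA1 were high in number 1, IL7R at 251 against 98.0 to 106 CPM (0.949) and DNAJA1 at 927 against 645 to 692 CPM (0.832). IL3RA was low in number 4 (1.82 against 2.72 to 2.78 CPM, 0.937). With saline IL13 was found in number 3 alone (0.213 CPM, 1 of the range) and EBI3 in number 1 alone (0.129 CPM, 1 of the range). These values rest on 2 reads of IL13 and 1 read of EBI3.

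In library 2_1 of the IL-33 cells 24828 genes were detected against 17775 to 20104 in the other 6 libraries, a gap of 0.670. This library was among 4 that stood apart on the first principal component of the 15 peripheral blood-derived libraries, which held 40.7% of the variance. Scores were 58.8 for saline 1_1, 97.6 for IL-33 2_1, 93.8 for IL-33 2_2 and 86.0 for IL-33 4_1, and at most 3.2 for the others. A lower depth was argued against, since with every library thinned to 1107816 reads the gap stayed at 32.3% of the range or more in 10 draws (36.4% with all reads). That these libraries produce the IL-33 calls was argued against too, as 378 of the 396 genes kept their call and direction without them. The 4 libraries also had more counts of some transcripts, which were chosen after their values were seen. DBET and REXO1L1P together had 119 to 632 CPM in them and at most 18.8 in the other 11. RN7SL pseudogenes with olfactory receptor genes took 0.103% to 0.423% of counts in them and at most 0.0624% in the other 11. Tissue libraries held 0.133% to 0.362% of the latter, so that share does not set these 4 apart in the series. What raised these counts was not tested. The 4 libraries include both treatments but are mostly IL-33 libraries. Both libraries of IL-33 number 2 are among them, so their removal takes that sample out whole. The design names no group that the 4 libraries share, and no biological explanation was tested.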

How the results depend on the processing

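Removal of the 4 peripheral blood-derived libraries that stand apart, and of IL-33 library 1_1 for IL2RA, was chosen after seeing the data, and the other alternatives were planned. SLC40A1 in peripheral blood-derived cells, not called at 0.15, went to -0.026 with libraries summed by the second number. No other named gene changed direction in any alternative that gave a value, and no called gene of CRSwNP against CRSsNP or of peripheral blood-derived cells did. In cord blood-derived cells 8 of 1519 did with transcript length offsets and 8 with limma-trend. IL2RA passed in CRSwNP against CRSsNP in each alternative (4.36 to 5.35 over left-out replicates, 4.86 with the replicate block) and in cord blood-derived cells (1.83 to 2.00, left out 1.88 to 1.93), and its difference between cultures passed in none (1.29 to 2.11). In peripheral blood-derived cells, where the filter removed IL2RA, its ratio was 9.92 to 20.5 over left-out numbers (exact permutation test, p = 0.0571 without a saline number), 9.23 without library 1_1 and 18.5 without the 4.

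The 95 genes of CRSwNP against CRSsNP became 331 with no low-count filter, 61 with transcript length offsets, 209 with DESeq2 and 44 with limma-trend. Leaving out a replicate gave 49 to 92, with 49 both without CRSwNP replicate 1 and without CRSwNP replicate 3. The 396 genes of peripheral blood-derived cells became 770 with DESeq2, 613 with the replicate block, 672 with 15 separate libraries, 755 with these and the block, and 145 with number 3 out of both groups. They became 662 without the 4 libraries and 1650 without them with the block. Leaving out a number gave 193 to 658, namely 251, 258, 220 and 193 without saline numbers 1 to 4 and 658, 260 and 208 without IL-33 numbers 2, 3 and 4. The 1519 genes of cord blood-derived cells became 769 with length offsets, 925 with DESeq2, 627 with limma-trend and 726 with a log2 fold change of at least 1, where the added condition shows the cause. Leaving out a library, which leaves 1 sample in a group that is assumed to vary like the other, gave 646 to 3233, namely 673 and 646 without saline 1 and 2 and 3233 and 2533 without IL-33 1 and 2. The 0 genes of the difference became 8 with no filter, 14 with the block and 48 without the 4 libraries, and 0 to 44 over left-out replicates, with 44 without IL-33 number 2. Samples that share only a number correlated by 0.096 to 0.22 in tissue, each best with its own, and -0.023 in cord blood-derived cells, and the block gave 126 and 1187 genes. In peripheral blood-derived cells it changed the calls of GATA2, MITF and MRGPRX2 and of no other named gene or list. Apart from the added fold condition, the cause was not tested.

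The 5 lists called in tissue became 0 with an estimated correlation and 0 with fry, the 10 in peripheral blood-derived cells became 3 and 6, and the 9 in cord blood-derived cells became 0 and 10. There fry gained 3 lists and lost 2, and the block gained T and NK cell markers (adjusted p = 0.046). Without the 4 libraries granule proteoglycan synthesis was lost (adjusted p = 0.325), interferon-stimulated genes were gained as lower (adjusted p = 0.0336), and the 3 became 0 (lowest adjusted p = 0.0799). The set of genes induced in peripheral blood-derived cells kept a median of 0.12 in CRSwNP with an estimated correlation but not its call (adjusted p = 0.27). Its medians were 0.11 to 0.23 over left-out replicates, and without CRSsNP replicate 1 it no longer passed (median 0.13). The cord blood-derived set had 0.30 for its top 100 genes, where its unadjusted p was under 0.05, and -0.044 to 0.093 over left-out replicates. Without CRSsNP replicate 1 it reversed to -0.01 with the test also pointing lower. Without CRSsNP replicate 2 its median was 0.08 and its unadjusted p was under 0.05. Without CRSwNP replicates 2 and 3 its medians were -0.01 and -0.04 while the test pointed higher. The cause was not tested.

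Besides IL2RA, which kept its call throughout, 31 named genes were called in tissue, of which 14 kept their call over all left-out replicates and 12 over all alternatives. GNAI1 lost it in all 6 such fits and RRP1B and ST3GAL6 in 5. Without CRSsNP replicate 1, MLC1, IL9R, GFRA1, OSM, AURKA, CHST15 and P2RY14 also did (adjusted p 0.060 to 0.178). Without CRSsNP replicate 2, MLC1, GFRA1, ABI3BP, BSPRY, SPTBN1, OSM, SOCS2, LIF, AURKA, CHST15 and P2RY14 did (0.051 to 0.270), and without CRSsNP replicate 3, IL10RA, SPTBN1, MAP3K8 and CHST15 (0.059 to 0.196). Without CRSwNP replicate 1, IL10RA, GFRA1, BSPRY, SPTBN1, OSM, SOCS2, LIF, MAP3K8 and CHST15 did (0.057 to 0.266), without CRSwNP replicate 2, ABI3BP, BSPRY, SPTBN1, MAP3K8, AURKA and P2RY14 (0.052 to 0.110), and without CRSwNP replicate 3, ABI3BP, SPTBN1, OSM, SOCS2, LIF, AURKA, CHST15 and P2RY14 (0.070 to 0.222). Of 15 named genes that did not pass, 11 passed in at least 1 alternative.

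Of 60 called in peripheral blood-derived cells, TNFRSF1B and CD200R1 aside, 41 kept their call over left-out numbers and 38 over all alternatives. CCL4, IRAK2 and VEGFA and others, 13, 9, 14 and 17 genes in all, lost it without saline numbers 1 to 4 (adjusted p 0.051 to 0.175), and 9 such as HS3ST1 and LPAR5 without IL-33 number 1 (0.050 to 0.121). Without IL-33 number 2 only CCL4 did (0.068), and without numbers 3 and 4, 11 and 15 genes such as CD40, HSPA6 and EGR1 (0.054 to 0.147). SQLE (0.83), GATA2 (1.42), MITF (-1.25) and IL1RL1 (1.05) passed without IL-33 number 2, as did the 10 genes of smallest p for the difference between cultures (adjusted p at most 0.032). Of 99 called in cord blood-derived cells, IL2RA, C15orf48, CD69 and REL aside, 61 kept their call over all alternatives. Fits without a library leave 1 sample in a group. Genes that lost their call without saline 1 or 2 had log2 fold changes under 1 in the fit of all libraries, except IFIT2, CCL5, DEFA3, SOCS2 and KLF7. IFIT2 lost it without IL-33 1 (0.070), and GLCE, CCL5, DEFA3 and IRAK4 without IL-33 2 (0.066 to 0.142). The median of all genes moved to -0.16 with limma-trend in cord blood-derived cells and to 0.19 with no filter in peripheral blood-derived cells.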

Other observations

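The tests of T and NK cells, of the depth behind IL2RA in peripheral blood-derived cells and of other myeloid cells were chosen after their results were seen, and the others before. Cord blood-derived cultures carried transcripts of other myeloid cells beside those of mast cells. With saline, S100A8 and S100A9, which encode the calprotectin subunits, stood at 1952 ± 72.9 and 1112 ± 35.3 TPM (SD, n = 2), and CLC, the Charcot-Leyden crystal protein gene of eosinophils and basophils, at 1063 ± 98.8 TPM. The neutrophil granule genes PRTN3, MPO and ELANE had 548, 459 and 159 TPM. In peripheral blood-derived cells with saline each of these was at 0.345 TPM or less. Tryptase, from TPSAB1, was at 12461 TPM in cord and 23969 TPM in peripheral blood-derived cells, and KIT at 963 and 1700 TPM. With IL-33, CLC was at 664 TPM in cord blood-derived cells and S100A8 at 1860 TPM.

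CD3D, CD3E and TRAC, which encode T cell receptor complex chains, had 0.257, 0.555 and 0.500 CPM in CRSwNP against 0.267, 0 and 1.54 CPM in CRSsNP mast cells, TRBC1 had 0.250 against 0 and CD2 0.353 against 5.56. CD3E was higher by 0.555 ± 0.106 CPM (SE). Mitochondrially encoded genes took 11.7% to 14.8% of counts in CRSwNP and 7.86% to 12.5% in CRSsNP libraries.

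IL2RA was higher in CRSwNP than in CRSsNP mast cells, and T and NK cells in the CRSwNP samples could raise it. Their 19 summed markers, of which 4 were high enough to be tested in these cells, rose by 10.999 ± 24.9 CPM (SE) while IL2RA rose by 103 ± 20.6 CPM. CTSW, a gene of cytotoxic T and NK cells outside that list, rose by 93.6 ± 21.3 CPM, and with it the sum rose by 105 ± 25.4 CPM, as much as IL2RA. The 8 cytotoxic markers of the list rose by 14.6 ± 22.8 CPM, below IL2RA by 88.5 ± 18.6 and below CTSW by 79.0 ± 35.5. These values argue against T and NK cells that carry the listed markers as the source of the whole rise, and cells that carry CTSW without them stay open. A different depth was argued against as well, since with every library thinned to 1575486 counts the log2 fold change was at least 4.71 and adjusted p at most 0.00508 in 10 draws. Carriers of IL2RA outside the marker lists, and a difference in the isolation of the tissue cells, which is not given in the sources used here, stay open and untested. Disease is the biological difference that the design names.

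IL2RA was near the floor in peripheral blood-derived cells with saline and at 86.9 TPM in cord blood-derived cells. Depth was argued against, as the cord blood-derived rate predicts 5971 reads where 4 were seen (95% counting bound 10.2). A transcript index without IL2RA is argued against, as all 7 peripheral blood-derived IL-33 libraries assigned reads to this gene. Its average effective length in them was 610 to 2916 bases, against 1815 to 2169 bases in cord blood-derived libraries. Any other difference of the transcript index behind the tables cannot be told apart from a difference between the cells. Of 2270 genes at 50 TPM or more in cord blood-derived cells, 37 (1.63%) were under 1 TPM in peripheral blood-derived cells. This is above the bound of 1% set for excluding a different index. Among the 37 were IL2RA itself and S100A8, CLC, PRTN3, MPO and ELANE, so a difference between the cells alone can exceed that bound and the count does not bear on the index. Spearman's rho across genes, which are not independent replicates, was 0.881. Other myeloid cells in the cord blood-derived cultures may carry IL2RA, and this stays open, with 46 markers of neutrophils, monocytes and eosinophils or basophils summing to 12783 TPM against 662 TPM and 29 against 4 of them at 10 TPM or more, although purity by toluidine blue staining was a condition of these cultures and their origin is itself a group of the design.

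Other splits of the samples were refitted. In CRSwNP against CRSsNP the 10 possible splits are too few for a share under 0.05. The real split called 95 genes and the highest other split 2, so 1 split gave as many, and the real split called 5 lists where the highest other called 9, with 4 splits giving as many. For the set of IL-33-induced genes the real split gave a -log10 p of 3.30 and the highest other 3.37, with 2 splits giving as much. Among 35 splits of the peripheral blood-derived samples only the real one, 1 split, called 396 genes, and the highest other called 3. That share is under 0.05 only over splits that ignore the possible pairing of the samples. Every other split mixes the treatments, so a treatment effect adds to the spread within its groups. If the pairs hold, chance is not excluded for genes. For lists it is not excluded either way, as 4 of 35 splits called 10 lists or more, with 11 as the highest other. The 8 splits that part all 4 pairs of samples with the same first number are too few for a share under 0.05, and the 7 others called 0 genes in edgeR where the real one called 396.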
